A study of Haliotis discus hannai with 28 samples.

How the data were processed

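RNA was measured by poly(A)-selected, strand-preserving RNA sequencing of the hepatopancreas (the digestive gland) and the mantle (the tissue that lines and builds the shell) of Pacific abalone, Haliotis discus hannai, per the labels' protocols. Each of the 28 libraries had a table with 47532 loci, the same loci in each. Per the submitters' processing notes, HISAT2, SAMtools, Subread and featureCounts were used; their versions, the order of the steps, the strand setting of the counting and the treatment of reads with several matches were not given in the sources used here. Reads of overlapping or antisense loci, and of near-identical members of a gene family, could therefore have been shared between loci, and values of single members of a large family are uncertain to that extent.

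The deposited tables gave 2 measurements per locus. The authors' read counts are whole numbers that were not normalized, per the file headers and the values. The authors' RPKM values were recomputed from the counts: they use the locus's whole genomic span, introns included, as the length and all counted reads of the library as the total, with a largest relative deviation of 1.1e-06. The median span was 5663 bp and the median coding length 759 bp, so these RPKM values are low for genes with long introns and were used only for filters and as an alternative test. The tables also held a coding DNA sequence per locus under a column headed as amino acid sequence; 97.6% of these translated in frame 1 without an internal stop. Scaffold names and positions are those of the assembly that the file headers name.

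The files pair no gene names with the locus identifiers. Lists of product names fixed before the data were examined could therefore not be applied, and loci were placed in sequence families instead. The coding sequences were translated, and 133 families were written as residue signatures or as short conserved reference stretches from textbook knowledge, after the tables were opened and before any growth comparison was run. A reference stretch was matched with blastp 2.17.0+ at an e-value of at most 1e-10, with an identity of at least 45% over at least 60% of the stretch. Each family was also matched against shuffled proteins, and 96 families with shuffled matches of at most 10% of their matches were used, which placed 1285 loci in at least 1 family. Families were joined into lists of related function. The family of a locus is a match to a signature, not an annotation of the locus, and families miss members that lack the signature. Classes for vitellogenin-type proteins, strict baculoviral IAP repeats and secreted low-complexity proteins were written after the growth comparisons had been seen.

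Growth groups were compared with edgeR 4.0.16 in R 4.3.3 on the counts: filterByExpr by group, TMM scaling factors, robust dispersions and the quasi-likelihood F test, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Each tissue was fitted on its own 14 libraries. The difference of the growth effects between the tissues and the difference between the tissues were contrasts of 1 fit to all 28 libraries. A log2 difference was computed as high growth minus low growth, or mantle minus hepatopancreas, and its standard error was taken from the size of the difference and its F statistic. CPM values use the TMM-scaled library total and are means, with ± SD where given. For a growth comparison the scaling factors come from the 14 libraries of the tissue, and for the difference between tissues and for the tissues from all 28, so a locus can have other CPM values there. Values of the vitellogenin-type loci, and of the loci that followed them, are CPM of the unscaled total. Lists with at least 5 tested members were tested with camera in limma 3.58.1, against all other loci, with an inter-gene correlation preset at 0.01 and, beside it, estimated for each list, and with adjustment over the lists. Beside each list that passed, the value with the estimated correlation is given. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.

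By the rule for single loci, which was fixed before the data were examined, 2 loci that rose and 2 that fell are identified per comparison, by smallest p among those with a mean of at least 1 RPKM (for the tissues, by abundance). Up to 4 members per list that passed, by smallest p, or otherwise the 2 most abundant members, are described by family without an identifier. Loci outside this rule are said to be so.

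The libraries held 27046969 to 36703116 counted reads in the hepatopancreas and 21722841 to 32204959 in the mantle. A count of 3 reads, the upper limit that a count of 0 allows, was between 0.0817 and 0.138 CPM of the unscaled total. That floor covers counting error only, since the reads carried no molecular identifiers. The fits were tested on simulated data with the real means and library totals and 200 changed genes. In the simulated hepatopancreas comparison on 24269 genes, 17% of the genes with a 2-fold change and 84% of those with a 4-fold change were recovered, with 5 false calls. In the simulated mantle comparison on 25915 genes these shares were 11% and 73%, with 1 false call. For the difference between tissues, on 29519 genes, they were 3% and 39%, with 1 false call, and for the tissues, on 29521 genes, 57% and 84%, with 5 false calls. In both simulated growth comparisons camera called a raised list of 25 genes and 0 of 20 unchanged lists. Every gene of the raised list had been raised 2-fold or 4-fold, so its call was to be foreseen. The simulated genes varied independently of each other. The 0 of 20 therefore does not give the rate of false calls for lists whose members vary together, as in the real data.

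Alternatives were DESeq2 size factors within edgeR, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1) with a mean of at least 0.5 RPKM, 1 fit to all 28 libraries, the replicate number as a block, a fold bound and each library left out in turn. Total reads without scaling factors, an offset for GC content and coding length, and the level of the vitellogenin-type loci as a covariate were added after the data were seen. No library was left out of the comparisons, and no pair of libraries held identical values.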

Results

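Gene expression was measured in Pacific abalone from 1 breeding population that had been reared and then sorted by growth. The labels describe 7 animals of a high-growth group and 7 of a low-growth group, chosen near their group's mean, with hepatopancreas and mantle sampled from each. The 28 libraries therefore formed 4 groups of 7, and replicates of a group were separate animals. Counted reads per library ranged from 27046969 to 36703116 in the hepatopancreas and from 21722841 to 32204959 in the mantle. Of the 47532 loci, 43125 had a read in at least 1 library. Replicates of a group had a median pairwise Spearman rho across loci of 0.902 and 0.929 in the high- and low-growth hepatopancreas, and of 0.923 and 0.888 in the high- and low-growth mantle. Genes are not independent replicates in these correlations.

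In the mantle, the first principal component held 36.5% of the variance, and all 7 high-growth libraries scored above all 7 low-growth libraries. In the hepatopancreas it held 21.6%, and high-growth replicate 2 scored −53.0, within the range of the low-growth libraries (−72.5 to −22.9). High-growth replicate 7 scored −19.6, next to that range, and the other 5 high-growth libraries scored 22.7 to 109.8.

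**Figure D1:**
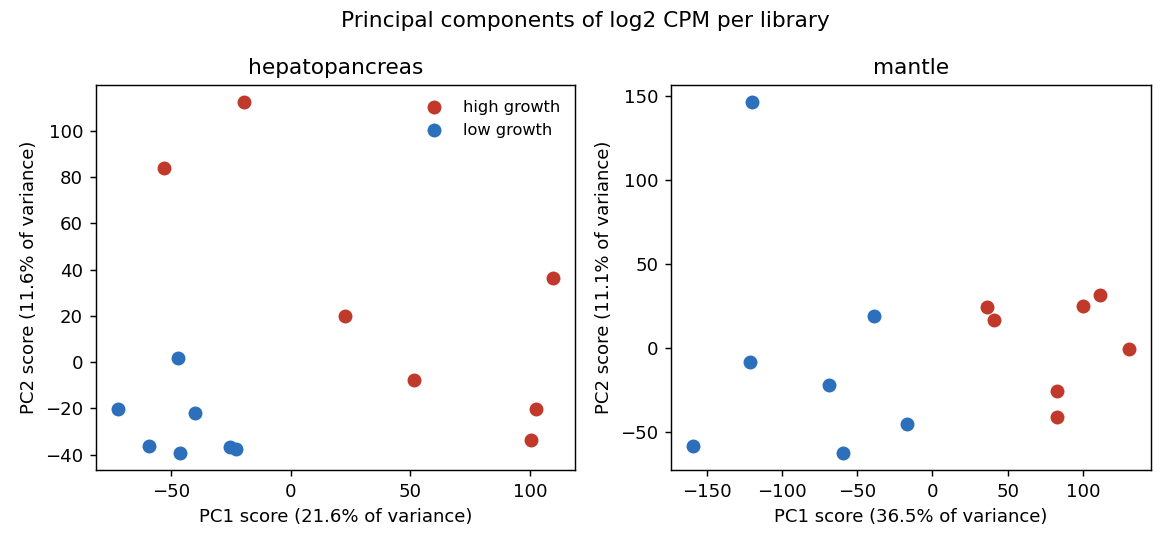
Scores of each library on the first and the second principal component of log2 CPM, computed per tissue, with high-growth libraries in red and low-growth libraries in blue. In the mantle the groups lie apart on the first component (36.5% of the variance), while in the hepatopancreas (21.6%) high-growth replicate 2 lies among the low-growth libraries.

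The growth comparison in the hepatopancreas asked which genes differed in the digestive gland between fast- and slow-growing animals. Few genes did by the main fit, and most of them were lower in the high-growth animals: of 24843 tested loci, 40 rose and 164 fell. The split depended on the fit, with 549 and 601 by DESeq2's Wald test, 227 and 280 in a fit to all 28 libraries and 56 and 49 with the vitellogenin-type level as a covariate. Loci that matched protease and lipase families were among those that fell. So were sulfotransferases, which transfer sulfate groups to small molecules and sugars. The summed level of 2 loci that resemble egg-yolk protein genes was strongly raised in 5 of the 7 high-growth animals, and 1 of these loci passed. At an unadjusted p under 0.05, 3269 loci differed, and 35 of the loci that rose and 148 of those that fell changed at least 2-fold.

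The locus HDIH07586CG0130 (scaffold HDIH07586, 881024 to 883060) rose by 2.95 on the log2 scale (SE 0.37, adjusted p = 0.0017), from 18.5 ± 8.22 CPM in low growth to 142.1 ± 59.2 CPM in high growth (SD, n = 7 each). It lay above the low-growth median in 7 of 7 high-growth libraries. HDIH02871CG0360 (scaffold HDIH02871, 1518530 to 1528268) rose from 113 ± 33.5 to 525 ± 237 CPM, a log2 difference of 2.21. Among the loci that fell, HDIH18898CG0790 (scaffold HDIH18898, 2840137 to 2844831) had 81.3 ± 27.6 CPM in high growth against 493 ± 135 CPM in low growth, and HDIH18898CG0850, on the same scaffold at 2968472 to 2973366, had 66.1 ± 22.3 against 341 ± 74.0 CPM. Both had an adjusted p of 0.00047 and lay below the low-growth median in every high-growth library. None of these 4 loci matched a sequence family, and the files do not pair their identifiers with gene names.

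Of 58 tested loci of digestive proteases and lipases, 0 rose and 5 fell. Adjusted over the list alone, 1 rose and 13 fell, and with total reads in place of the scaling factors 0 rose and 10 fell. A family match alone does not show that a locus acts in digestion. Carboxylesterases, relatives of bile salt lipase that split esters, gave 2 of the 5: a log2 difference of −1.72 (SE 0.25), with 16.0 ± 6.13 against 52.7 ± 12.7 CPM, and of −1.18, with 49.6 ± 11.6 against 113 ± 31.2 CPM. The product-name lists fixed earlier had placed carboxylesterases with antioxidant and detoxification enzymes, and bile salt-activated lipase with digestive ones. Astacin-like metalloproteases, zinc proteases of which many act in digestion, gave another 2 of the 5. One fell from 282 ± 98.1 CPM in low growth to 105 ± 35.3 CPM in high growth and the other from 64.7 ± 22.8 to 21.1 ± 11.2 CPM, and the median over the 13 astacin loci was −1.23. The fifth was a locus of the pancreatic lipase family with a log2 difference of −3.07, named here after its value was seen. The list as a whole lay lower in high growth in the camera test (adjusted p = 0.00085), with adjusted p = 0.25 with an estimated correlation. The 41 loci of enzymes that digest algal polysaccharides, such as cellulases and sulfatases, held none that passed. Laminarinase-like enzymes and alpha-amylases were not in this list, since their signatures matched shuffled proteins too often. No signature was written for alginate lyases, so the digestion of algae was tested only in part. The 2 most abundant cellulases had 1513 ± 543 and 2711 ± 1359 CPM in high growth against 1328 ± 737 and 2821 ± 1562 CPM in low growth.

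Sulfotransferases numbered 31, of which 0 rose and 3 fell (2 rose and 4 fell adjusted over the list alone). The most abundant of the 3 fell from 53.8 ± 10.1 to 23.4 ± 6.79 CPM, a log2 difference of −1.20, and the other 2, at −2.36 and −1.86, had under 3 CPM in both groups. The list was lower in high growth at an adjusted p of 0.038, with adjusted p = 0.47 with an estimated correlation. Lipid metabolism and glycolysis were the lists that lay higher. In neither did a member pass on its own (lipid metabolism 3 higher and glycolysis 1 higher adjusted over the list alone), and the list tests gave adjusted p = 0.0071 and 0.038. With an estimated correlation, adjusted p = 0.28 for each. The glycolysis list also held 3 arginine kinases and related phosphagen kinases, which are not enzymes of glycolysis. These had a median log2 difference of 1.87 (0.21 to 3.67), against 0.07 to 0.61 for the glycolytic enzymes. The stearoyl-CoA desaturase, which makes monounsaturated fatty acids, had 177.5 ± 87.1 CPM in high growth against 83.5 ± 11.8 CPM in low growth (adjusted p = 0.081), and glyceraldehyde-3-phosphate dehydrogenase of glycolysis had 753 ± 281 against 499 ± 102 CPM (adjusted p = 0.29). The 9 ligands of the TGF-beta family, secreted growth and differentiation factors, had a median of −0.32 with none past the threshold (1 lower adjusted over the list alone). Their list gave adjusted p = 0.038, and adjusted p = 0.25 with an estimated correlation. Outside these lists a cytochrome P450 (−1.40), a locus with EF-hand calcium-binding motifs (−3.71) and a serine/threonine kinase (−0.76) fell. The most abundant collagen had 3645 ± 886 against 1358 ± 746 CPM and did not pass (adjusted p = 0.075).

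Vitellogenins are the yolk precursor proteins of eggs. The 2 vitellogenin-type loci, looked for after the growth comparison had been seen, summed to a median of 32.3 CPM in high-growth hepatopancreas (0.732 to 603) and of 1.37 CPM in low-growth hepatopancreas (0.533 to 1.92). One of them rose, with a log2 difference of 9.84 (SE 1.87, adjusted p = 0.025, above the low-growth median in 6 of 7). The other did not pass (3.94, adjusted p = 0.054). High-growth replicates 2 and 7, the pair that scored next to or among the low-growth libraries on the first principal component, had 0.732 and 2.05 CPM, and the other 5 had 16.1 to 603 CPM.

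**Figure D2:**
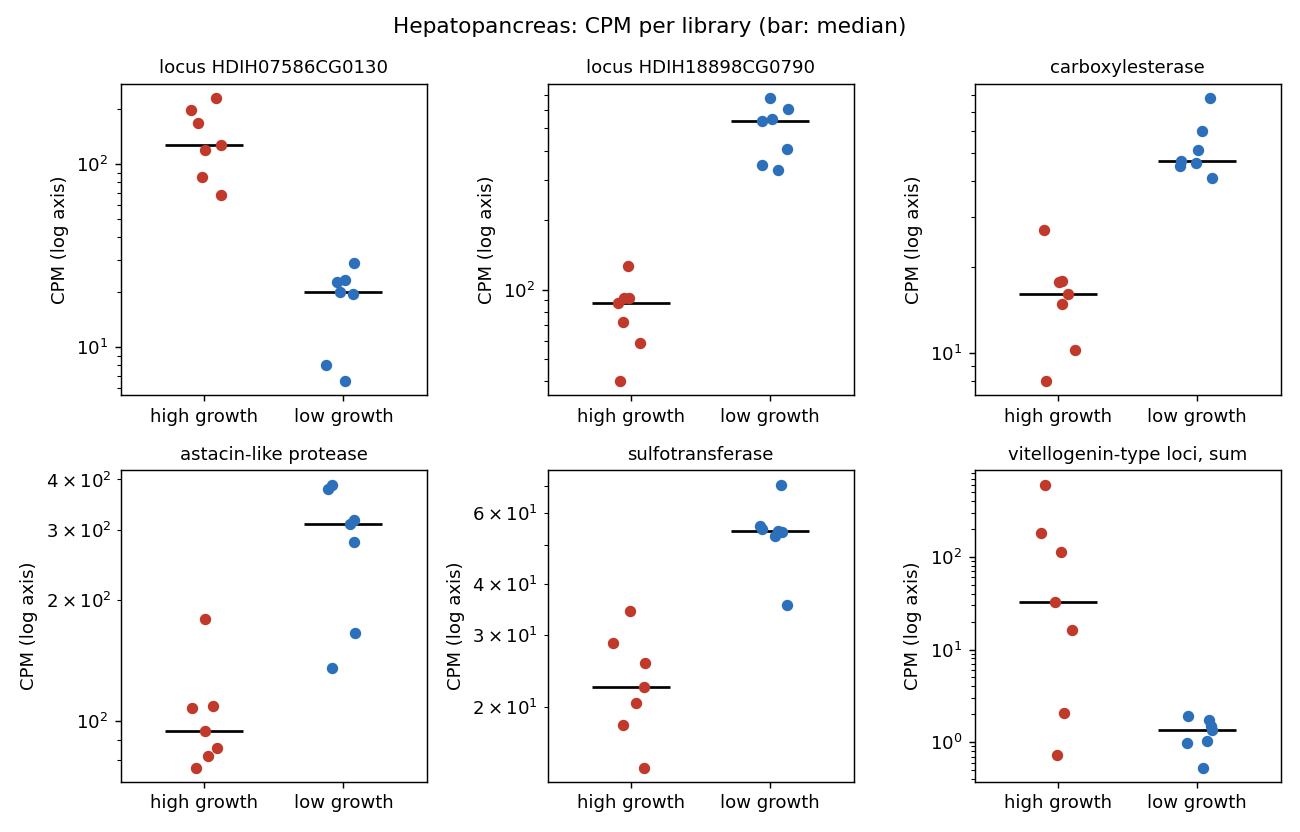
CPM on a log axis for each of the 7 high-growth (red) and 7 low-growth (blue) hepatopancreas libraries, for 5 loci and for the sum of the 2 vitellogenin-type loci, with a bar at the median. The sulfotransferase lies between 14.2 and 34.4 CPM in high growth and between 35.5 and 70.4 CPM in low growth, while the vitellogenin-type sum spreads from 0.732 to 603 CPM among the high-growth libraries.

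The count of 204 depended on the fit: DESeq2's Wald test gave 1150, a fit to all 28 libraries 507, limma-trend on log2(RPKM + 1) 320, the fit with the vitellogenin-type level as a covariate 105 and the fit with the replicate number as a block 39. The block joins high- and low-growth libraries of different animals. Libraries that share a number across the growth groups did not deviate together in either tissue. Without low-growth replicate 2, 3, 4, 6 or 7 the count was 107, 80, 121, 125 or 133.

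The same comparison in the mantle asked which genes differed with growth in the shell-building tissue. Differences were widespread: of 26414 tested loci, 4611 rose and 4420 fell in high growth, and 3118 and 2472 of these changed at least 2-fold. Genes for Kunitz-type protease inhibitors, receptor tyrosine kinases, nuclear hormone receptors and collagens rose more often than they fell. Families tied to shell building went both ways, with more rises than falls, and neither their list nor that of collagens and other matrix loci passed. All 11 tested ribosomal protein genes fell, by a median of 0.87 on the log2 scale (9 fell, by a median of 0.50 over the 11, with total reads alone). Sulfotransferases, caspases and immunity-associated GTPases that changed fell, and 2 heat shock protein 70 genes dropped by more than 2 log2 units.

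The locus HDIH03253CG0230 (scaffold HDIH03253, 836835 to 837737) rose from 0.143 ± 0.119 to 9.25 ± 2.51 CPM (SD, n = 7 each), a log2 difference of 6.01 (SE 0.53, adjusted p = 7.4e-05). HDIH16052CG0210 (scaffold HDIH16052, 660998 to 664144) rose from 1.70 ± 0.88 to 31.6 ± 13.1 CPM. HDIH13695CG0730 (scaffold HDIH13695, 2896794 to 2905180) fell from 37.7 ± 9.34 to 9.09 ± 2.94 CPM, and HDIH20933CG1390 (scaffold HDIH20933, 6129898 to 6142819) from 50.5 ± 12.3 to 13.6 ± 3.57 CPM. The last of these matched the strict signature of a baculoviral IAP repeat, the domain of inhibitor of apoptosis proteins, a class written after this result was seen. In each of the 4 loci, all 7 high-growth libraries lay on the same side of the low-growth median.

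Of 24 Kunitz-type protease inhibitors, small secreted proteins that block serine proteases, 12 rose and 2 fell (14 and 4 adjusted over the list alone). The 3 leading ones had large rises: 320 ± 319 against 3.72 ± 2.91 CPM (log2 6.42, SE 0.82), 787 ± 423 against 21.5 ± 26.4 CPM (5.19) and 75.4 ± 37.4 against 2.58 ± 2.71 CPM (4.86). Another fell, with 9.54 ± 3.06 against 34.2 ± 19.4 CPM. The list was higher in high growth at an adjusted p of 0.013, with adjusted p = 0.51 with an estimated correlation.

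Of 47 loci in families of shell formation, 14 rose and 6 fell (15 and 6 adjusted over the list alone, 17 and 2 with total reads alone). The list did not pass (adjusted p = 0.092, and adjusted p = 0.51 with an estimated correlation). Chitinases, which cut chitin such as that of the shell's organic framework, gave 4 that rose and 1 that fell of 16. Among them were loci with 64.6 ± 42.1 against 2.44 ± 2.09 CPM (log2 4.73) and 300.2 ± 69.98 against 68.3 ± 43.0 CPM (2.14). The first appears to be the leading chitinase of the difference between the tissues, below, which was far more abundant in the hepatopancreas. The family match alone does not tie it to the shell. Among 9 carbonic anhydrases, which turn carbon dioxide into bicarbonate, 4 rose and 1 fell, and the leading locus had 270 ± 192 against 14.8 ± 13.9 CPM (4.19, SE 0.75). A calcium-pumping ATPase rose from 71.9 ± 22.7 to 196 ± 52.5 CPM, and 3 of the 5 loci of this family rose while 1 fell. Of 2 tyrosinases 1 rose, with a log2 difference of 3.45, named here after its value was seen. Chitin synthases (1 rose and 2 fell of 8) and perlucin-like lectins (1 rose and 1 fell of 5) went both ways. Collagen and other extracellular matrix loci gave 8 that rose and 1 that fell of 24 (8 and 1 adjusted over the list alone), and their list did not pass (adjusted p = 0.092, and adjusted p = 0.57 with an estimated correlation). The leading collagens had 154 ± 47.3 against 27.1 ± 14.9 CPM and 74.3 ± 23.4 against 13.7 ± 7.45 CPM.

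**Figure D3:**
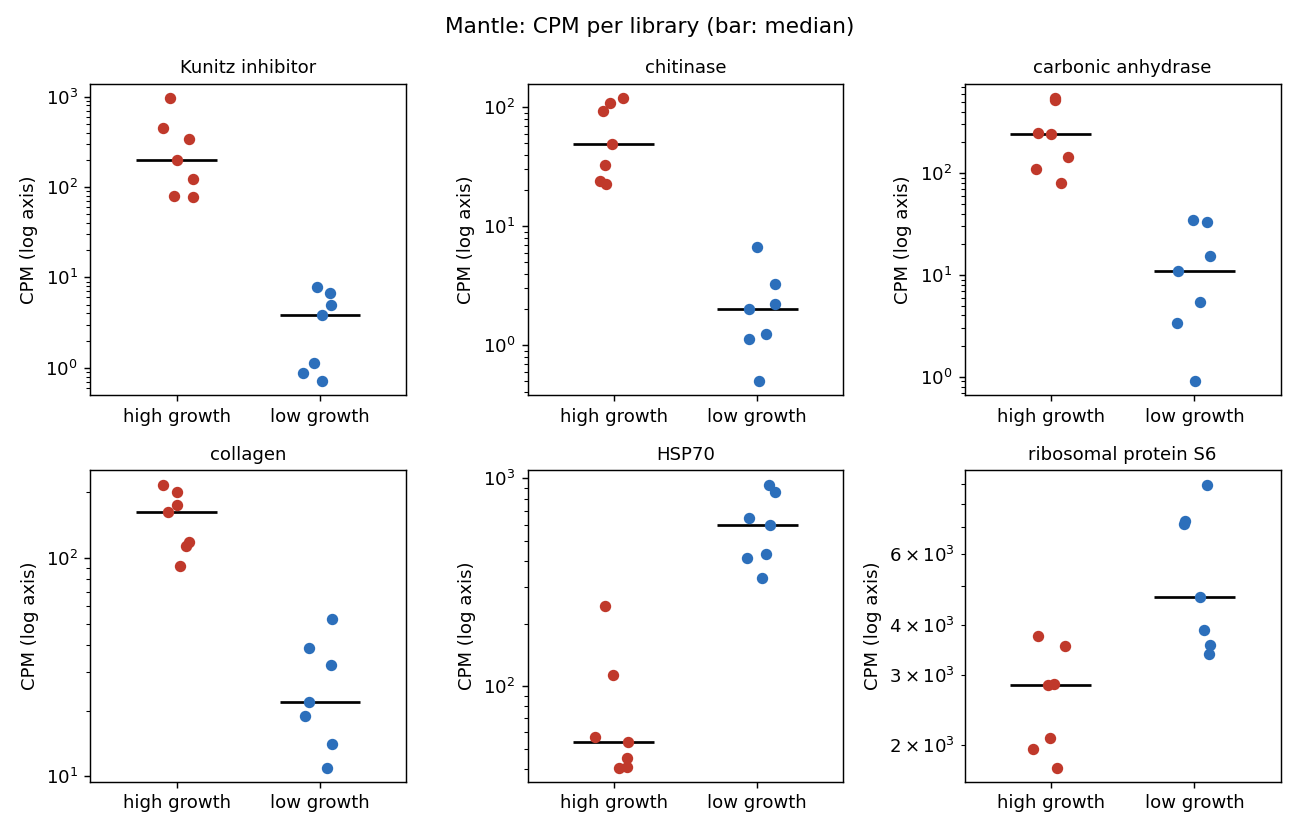
CPM on a log axis for each of the 7 high-growth (red) and 7 low-growth (blue) mantle libraries, for the leading locus of 5 families and for ribosomal protein S6, with a bar at the median. The Kunitz inhibitor lies between 77.7 and 969 CPM in high growth and between 0.72 and 7.84 CPM in low growth, and the heat shock protein 70 gene between 40.6 and 244 against 333 and 935 CPM.

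Signalling kinases were the list with the most changes, with 51 that rose and 23 that fell of 141 (58 and 25 adjusted over the list alone). Receptor tyrosine kinases, the receptors of many growth factors, contributed 17 that rose and 1 that fell of 29, led by a locus with 36.9 ± 12.8 against 7.74 ± 3.72 CPM (log2 2.25, SE 0.34). Serine/threonine kinases went both ways, with 34 that rose and 22 that fell of 112. With total reads in place of the scaling factors the whole list gave 58 that rose and 6 that fell. The list was higher in high growth at an adjusted p of 0.0058, with adjusted p = 0.57 with an estimated correlation. Nuclear hormone receptors, transcription factors that respond to small molecules, gave 9 that rose and 1 that fell of 20 (11 and 1 adjusted over the list alone). The 4 with the smallest p rose by 1.12, 1.83, 2.06 and 3.59 on the log2 scale, and the list gave adjusted p = 0.0071, and adjusted p = 0.51 with an estimated correlation. TGF-beta family ligands changed in both directions, with 2 that rose and 2 that fell of 12.

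Ribosomal proteins were the list with the lowest p among those that fell: 11 of 11 loci passed (also adjusted over the list alone). Ribosomal protein S6 had 2678 ± 782 against 5546 ± 2206 CPM, and S13 had 1165 ± 317 against 2449 ± 712 CPM (log2 −1.07, SE 0.22). For S6 the groups overlapped, with up to 3753 CPM in high growth and from 3369 CPM in low growth. Low-growth replicates 2, 5 and 7 had the highest S6 levels (8951, 7244 and 7136 CPM). They also had the lowest scaling factors of the mantle libraries (0.741, 0.748 and 0.703). The list's adjusted p was 0.00076, and with an estimated correlation of 0.905 among its members the adjusted p = 0.57. Outside the lists tested, the ATP synthase beta subunit (−0.69), cytochrome c (−0.84) and 3 of 4 proteasome subunits fell. Glycolysis gave 2 that rose and 0 that fell of 8 (1 and 0 adjusted over the list alone), and its list did not pass (adjusted p = 0.86). Of these 2, 1 was of the arginine kinases and related phosphagen kinases. Lipid metabolism gave 0 that rose and 3 that fell of 11, including the stearoyl-CoA desaturase (−0.68). The median of that list was −0.27 and turned to 0.06, with 0 that fell, when total reads replaced the scaling factors.

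Of 25 sulfotransferases, 0 rose and 10 fell (0 and 11 adjusted over the list alone), by 1.39, 2.00, 1.56 and 0.87 for the 4 with the smallest p. With total reads alone, 0 rose and 4 fell. The list's adjusted p was 0.0071, and adjusted p = 0.57 with an estimated correlation. Of 92 loci of innate immunity, 5 rose and 23 fell (4 and 21 adjusted over the list alone), with a median of −0.35. With total reads alone, which moved the median of all loci up by 0.30, 7 rose and 11 fell, with a median of −0.03. Caspases, proteases of programmed cell death, gave 0 that rose and 9 that fell of 23, and immunity-associated GTPases of the AIG1 family 0 and 6 of 16, led by a locus with 84.7 ± 19.1 against 206 ± 66.3 CPM. C-type lectins went both ways, with 3 that rose and 4 that fell of 29. The 2 leading ones rose from 40.7 ± 20.9 to 165 ± 48.9 CPM and from 9.96 ± 6.27 to 53.9 ± 33.4 CPM. The immunity list's adjusted p was 0.035, and adjusted p = 0.51 with an estimated correlation. Heat shock and other chaperones, with 8 that rose and 5 that fell of 31, did not pass as a list (adjusted p = 0.31). Within it, 2 heat shock protein 70 genes fell from 602 ± 228 to 84.9 ± 74.6 CPM and from 3055 ± 1499 to 235 ± 264 CPM, and 1 of the other 2 rose. Of 14 DnaJ co-chaperones 4 rose and 2 fell, and of 11 protein disulfide isomerases 4 rose and 0 fell.

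The vitellogenin-type loci were low in the mantle and differed between the groups there too, with summed medians of 6.81 CPM (2.24 to 47.2) in high growth and 0.68 CPM (0.287 to 0.957) in low growth. Both loci rose, by 5.22 (adjusted p = 0.0025) and 2.57 (adjusted p = 0.0032). Muscle contractile loci gave 3 that rose and 0 that fell of 11, with a median of 0.29. Between the tissues, 5 of the 11 were higher in the mantle and 4 in the hepatopancreas, so they do not mark mantle muscle alone.

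**Figure D4:**
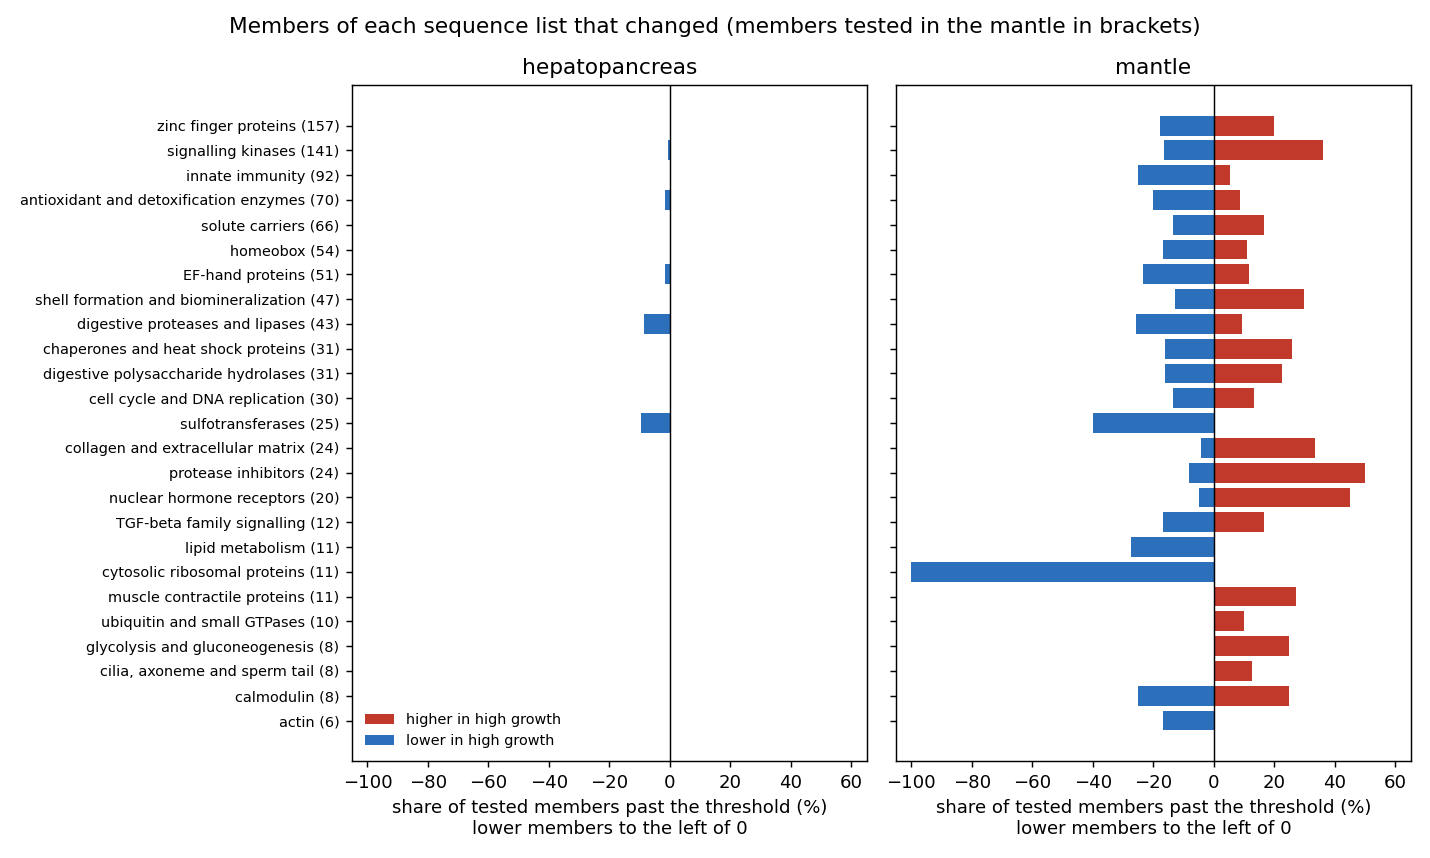
Share of the tested members of each list of sequence families that were higher (red, to the right) or lower (blue, to the left) in high growth, in percent, in the hepatopancreas and the mantle. All 11 ribosomal protein loci were lower in the mantle and none passed in the hepatopancreas, while Kunitz-type protease inhibitors had 12 higher and 2 lower of 24 in the mantle.

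The mantle count was 5855 (4095 higher and 1760 lower) with limma-trend on log2(RPKM + 1), 5274 (2895 and 2379) with the replicate number as a block, and 1974 (1396 and 578) with the vitellogenin-type level, which itself parts the groups, as a covariate. Total reads without scaling factors moved the median of all loci by 0.30 on the log2 scale and the split to 5560 higher and 2027 lower, so directions hold relative to that choice.

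The difference between the tissues asked whether genes responded to growth group in the same way in both. It passed for 3392 of 30226 tested loci. The signed log2 difference, high minus low growth, was higher in the mantle than in the hepatopancreas for 1484 and lower for 1908. A lower value can come from a fall in the mantle or a rise in the hepatopancreas. These counts therefore do not rank the tissues by the size of their response. This fit took the libraries as independent, although both tissues came from the same animals. With the animal as a block, by growth group and replicate number, 3554 passed, 1801 and 1753 of them, and 2603 of the 3392 were kept, so the balance of the directions depended on the fit. HDIH03282CG0750 (scaffold HDIH03282, 2621234 to 2632988) had 369 CPM in high-growth and 34.1 CPM in low-growth mantle, against 63.0 and 97.1 CPM in the hepatopancreas, a difference of 4.06 (SE 0.40, adjusted p = 3.1e-06). HDIH02836CG0320 (scaffold HDIH02836, 1147861 to 1157661) differed by 1.93. HDIH02871CG0350 (scaffold HDIH02871, 1510937 to 1513590) had 7.44 and 17.8 CPM in high- and low-growth mantle and 49.8 and 13.4 CPM in the hepatopancreas (−3.16), and its neighbour HDIH02871CG0360 differed by −2.66.

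Ribosomal protein genes stood out among the lists: 8 of 11 differed (11 adjusted over the list alone), with a median of −1.27. Ribosomal protein S14 had 1945 and 3661 CPM in high- and low-growth mantle and 3794 and 2407 CPM in the hepatopancreas. The list's adjusted p was 1.3e-05, and adjusted p = 0.49 with an estimated correlation. Lipid metabolism also differed downward, in 4 of 11 loci (4 adjusted over the list alone), with an adjusted p of 0.017, and adjusted p = 0.18 with an estimated correlation. The stearoyl-CoA desaturase had 78.02 and 128 CPM in high- and low-growth mantle and 221 and 104 CPM in the hepatopancreas, a difference of −1.81 (SE 0.36). Shell formation differed upward, with 6 loci up and 1 down of 58 (6 and 1 adjusted over the list alone), an adjusted p of 0.044, and adjusted p = 0.18 with an estimated correlation. The leading chitinase, at 50.6 and 1.99 CPM in high- and low-growth mantle and 1744 and 2076 CPM in the hepatopancreas, differed by 4.93. Protease inhibitors (2 up and 3 down of 28, 3 and 3 adjusted over the list alone) gave adjusted p = 0.028, and adjusted p = 0.18 with an estimated correlation. Nuclear hormone receptors (2 up and 0 down of 22, 5 and 0 adjusted over the list alone) and signalling kinases (23 up and 12 down of 144, 30 and 17 adjusted over the list alone) gave adjusted p = 0.044 each, and adjusted p = 0.49 and 0.59 with an estimated correlation. DESeq2's Wald test gave 5223 loci in place of 3392.

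The growth effects in the tissues were also compared across loci, to see whether the same loci differed with growth in both tissues. Over the 22196 loci tested in both, the log2 differences had a Pearson r of 0.214 and a Spearman rho of 0.209, and 0.1845 and 0.111 over the 834 loci of at least 10 RPKM, across genes, which are not independent replicates. Both tissues came from the same animals, so chance values are shared between them. With the replicate number taken as the animal, 100 assignments of the growth labels to animals, the real one included, were compared. The r of mean log2 CPM differences was 0.230 for the real labels and at least as high in 64 of the 100, with a median of 0.255 over the permuted ones. The covariance of these differences was 0.127 for the real labels and 0.0036 to 0.111 for the permuted ones. Of the loci that passed in both tissues, 39 fell in both, 4 rose in both, 4 fell in the hepatopancreas and rose in the mantle, and 1 did the opposite. The overlap expected without a growth effect was not estimated, since the tissues share animals.

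The tissues themselves differed at most loci: of 30226 tested, 9785 were higher in the mantle and 9628 higher in the hepatopancreas. On the first principal component of all libraries, with 67.6% of the variance, the 14 mantle libraries scored 199 to 254 and the 14 hepatopancreas libraries −257 to −214. The most abundant loci past a log2 difference of 2 were HDIH13186CG0050 (scaffold HDIH13186, 150434 to 161508) and HDIH09387CG0230 (scaffold HDIH09387, 1012264 to 1046318) in the mantle, at log2 differences of 9.99 and 9.56. In the hepatopancreas they were HDIH02803CG0040 (scaffold HDIH02803, 284751 to 306639), with 25770 CPM in high-growth and 34970 CPM in low-growth libraries, and HDIH22192CG0010 (scaffold HDIH22192, 17193 to 36990), with 32000 and 16580 CPM.

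Digestive enzymes set the hepatopancreas apart. Of 45 polysaccharide-digesting enzymes, 33 were higher there and 9 in the mantle (33 and 9 adjusted over the list alone), and a cellulase had 3790 and 2969 CPM in high- and low-growth hepatopancreas against 1.14 and 4.17 CPM in mantle. Of 61 proteases and lipases, 42 were higher in the hepatopancreas and 17 in the mantle (42 and 17 adjusted over the list alone), among them a pancreatic lipase-family locus (−10.05) and a trypsin-like protease (−9.17). The lists' adjusted p were 4.2e-07 and 3.5e-06, and both passed with an estimated correlation (adjusted p = 0.005 each). Sulfotransferases were higher in the hepatopancreas in 25 of 31 loci and in the mantle in 3 (25 and 3 adjusted over the list alone; adjusted p = 2.9e-05, and adjusted p = 0.075 with an estimated correlation). Homeobox transcription factors were higher in the mantle in 36 of 60 and in the hepatopancreas in 11 (36 and 12 adjusted over the list alone; adjusted p = 0.00026, and adjusted p = 0.053 with an estimated correlation). Kunitz-type inhibitors were higher in the mantle in 18 of 28 and in the hepatopancreas in 6 (18 and 6 adjusted over the list alone). All 6 actins were higher in the mantle (6 adjusted over the list alone). The lists of these inhibitors and of the actins gave adjusted p = 0.031 and 0.0056, and adjusted p = 0.075 each with an estimated correlation. Lipid metabolism (8 of 11 higher in the hepatopancreas and 1 in the mantle, 8 and 1 adjusted over the list alone) and antioxidant enzymes (37 and 21 of 75, 38 and 21 adjusted over the list alone) gave adjusted p = 0.027 and 0.046, and adjusted p = 0.17 and 0.23 with an estimated correlation.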

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

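The family classes for egg-yolk proteins were written after the growth comparison had been seen, and the tests in this part were otherwise planned. Within groups of 7 libraries, 126 sets of values were searched for a library far from the rest (a gap over Dixon's 95% critical value as a share of the group's range). Among them were reads per library, loci detected, the loci with identifiers and the members described by the rule from lists that passed. In the mantle, the lists of shell formation, collagen and chaperones were searched too. Other described loci, such as the cellulases of the hepatopancreas, were not searched. In 4 of the 126 sets a library stood apart, fewer than the 1 in 20 that chance gives. High-growth hepatopancreas replicate 4 had the highest level of an astacin-like protease, 7.49 log2 CPM against 6.26 to 6.77 in the others (ratio 0.587). Low-growth hepatopancreas replicate 7 had the lowest level of the most abundant sulfotransferase that fell, 5.15 against 5.72 to 6.14 log2 CPM (0.570). Low-growth hepatopancreas replicate 6 had the lowest level of a TGF-beta family ligand, 0.38 against 1.57 to 2.39 log2 CPM (0.591). Low-growth mantle replicate 2 had the lowest level of the leading C-type lectin, 2.92 against 4.87 to 6.13 log2 CPM (0.609). No total of reads stood apart, and no vitellogenin-type sum did on the log2 scale of the search. In CPM without a log, these sums did in high-growth hepatopancreas replicate 1, 603 against at most 179.6 CPM (0.703), and in high-growth mantle replicate 3, 47.2 against at most 17.5 CPM (0.660).

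The growth effect differed between the tissues at 3392 loci by the test of the difference itself. In 40 drawn splits of the 14 animals into groups of 7, only the real split, 1 of 40, gave as many. The highest other gave 15, so chance is unlikely as the source of the count. Among loci with a higher signed difference in the mantle, HDIH03282CG0750 (4.06) and HDIH02836CG0320 (1.93) had the smallest p. Among those with a lower one in the mantle, HDIH02871CG0350 (−3.16) and HDIH02871CG0360 (−2.66) did. Among the lists, ribosomal proteins (adjusted p = 1.3e-05) and lipid metabolism (0.017) differed downward in the mantle, and protease inhibitors (0.028), nuclear hormone receptors (0.044), shell formation (0.044) and signalling kinases (0.044) upward, and none of them passed with an estimated correlation.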

How the results depend on the processing

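Total reads, the offset and the vitellogenin-type covariate were chosen after the data were seen; the other settings were planned. No described locus and no list that passed in a growth comparison reversed. The balance of calls did reverse. In the hepatopancreas (40 higher and 164 lower) it turned with the covariate (56 and 49), and between tissues with the block, below. In the mantle (4611 and 4420) it turned with DESeq2 size factors (4463 and 4611) and with DESeq2's Wald test (5398 and 5539). A fit to all 28 libraries gave 4730 and 4835 there. The lists for the difference between tissues were not rerun. The hepatopancreas count (204; 19.6% higher) was 1150 with DESeq2 (549 higher and 601 lower), 320 with limma-trend on log2(RPKM + 1), 507 with all 28 libraries (227 and 280) and 105 with the covariate, of which 36 were among the 204; the cause was not tested. Without 1 library it was 80 to 288, and 107, 80, 121, 125 and 133 without low-growth replicates 2, 3, 4, 6 and 7. The mantle count (9031) was 5855 and 5786 with limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1), 5590 with a 2-fold bound and 1974 with the covariate, which parts the groups; without 1 library it was 7064 to 9641. DESeq2 gave 5223 for the difference between tissues (3392). The tissue count and the Pearson r stayed within 1.5 times, and the Spearman rho (0.209) was 0.111 over loci of at least 10 RPKM. With an estimated correlation 0 lists passed in either tissue, against 5 and 6. Without 1 library, 2 to 7 lists passed in the hepatopancreas (2 without high-growth replicate 1 or 5, and 3 without high-growth replicate 3 or low-growth replicate 1, 2, 3, 4 or 7) and 5 to 7 in the mantle. Of the values for described loci under settings other than a left-out library, 27 lost their call, 5 gained it and 680 stayed on their side of the threshold in the hepatopancreas, and 164, 4 and 994 did in the mantle. All 16 for the difference between tissues and all 16 for the tissues stayed. Most simulated 2-fold changes with growth were missed (17% in the hepatopancreas and 11% in the mantle were recovered). The simulated data held few changed genes, which makes the adjusted p threshold stricter than where many genes change. In the real mantle 9031 loci passed, and 5590 of them had at least a 2-fold change. The 11% therefore does not give the share of 2-fold changes missed there.

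With the replicate number (in the 28-library fits, the animal) as a block, the counts were 39 in the hepatopancreas and 5274 in the mantle. They were 3554 for the difference between tissues and 19980 for the tissues. Of the 3554, the signed difference was higher in the mantle for 1801 and lower for 1753, against 1484 and 1908 in the main fit. High- and low-growth libraries of a number did not deviate together (r of −0.117 to 0.0696 in the hepatopancreas and −0.177 to 0.102 in the mantle, with 1 of 7 correlating best with its own number in each). Hepatopancreas and mantle libraries of a number did in high growth (r of 0.196 to 0.368, 7 of 7 best) and less uniformly in low growth (0.0019 to 0.283, 6 of 7 best), as a hint from the data only.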

Other observations

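The tests on muscle loci, IAP repeats, secreted low-complexity proteins and the splits of the list counts were chosen after the growth comparisons were seen, as were the fits with total reads, with an offset and with the vitellogenin-type level. A leading mantle locus that fell matched a baculoviral IAP repeat, which prompted a count of that class. Of 20 loci with the strict signature tested in the mantle, 13 fell and 2 rose in high growth, with a median of −1.42, and their summed level was 1229 CPM in high growth against 4294 CPM in low growth. Among all other loci 16.7% fell. The one-sided Fisher's exact test over loci gave p = 1.902e-06, with an odds ratio of 9.26, and includes the locus that prompted it. Loci of 1 family are not independent of each other, so this p is for loci and not for animals. In the hepatopancreas, 0 of 17 such loci passed in edgeR's test, and the difference of the class between the tissues was not tested. Caspases, the proteases that IAP proteins bind, fell in 9 of 23 loci in the mantle.

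Shell matrix proteins are often secreted and of low complexity, which gave a hypothesis that the test did not settle. Of 34 loci for such proteins in the mantle, 7 rose and 7 fell, with 4 and 1 beyond 4-fold and a median of −0.20. Their summed level was 3937 CPM in high growth against 816.5 CPM in low growth, while their median level was 3.25 against 3.215 CPM. The share that rose was 20.6%, against 17.0% among other secreted loci, and a larger share was not shown (one-sided Fisher's exact test, p = 0.357, with an odds ratio of 1.27).

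In the mantle 9031 loci differed with growth, against 204 in the hepatopancreas, from as many libraries. In 100 drawn splits of the 14 mantle libraries the real one alone, 1 of 100, gave as many loci and the highest other gave 6. In the hepatopancreas the real one alone, 1 of 100, gave 204 and the highest other 2. Chance is thus unlikely as the source of either count. Of the mantle calls, 91.3% were also called with an offset for GC content and coding length. After every library was thinned to the smallest total, 21722841 reads, 96.1% were. These values argue against both as the main source. Of the calls outside the 100 most abundant loci, 97.8% were also called without these loci. That decides little about the scaling, since TMM already sets aside the most abundant loci. Total reads alone kept 73.1% of the mantle calls. The muscle list held 5 of 11 loci higher in the mantle and 4 higher in the hepatopancreas, so it measures mantle muscle poorly. Another share of muscle in the sampled piece cannot be told apart from a change within cells. The muscle loci had a median of 0.29 but went from −0.42 to 1.15. The rule for this test was reworded after that value was seen: by its first wording, a median under 0.5 in size, 0.29 would have argued against muscle. With total reads alone the median was 0.61, past that bound. Tissue makeup beyond muscle, sex or maturity, the batch of each library and growth itself stay open, as untested. The vitellogenin-type sums of the mantle groups did not overlap (2.24 to 47.2 CPM in high growth, 0.287 to 0.957 CPM in low growth). With their level as a covariate 20.7% of the mantle calls were kept. Since that level parts the groups, this fit cannot tell growth from sex or maturity.

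Chance could not be excluded for the number of lists that passed with a preset correlation. In the hepatopancreas, 14 of 100 splits gave at least the real 5 lists, up to 9, and in the mantle 9 of 100 gave at least the real 6, up to 8. For the tissues, 1 of 40 splits that swapped the tissue labels of some animals, the real one, gave 19413 loci. The highest other gave 5057, so chance is unlikely as the source of that count.

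Egg-type RNA varied between the animals of the high-growth group. Outside the 2 vitellogenin-type loci, 36 loci followed them across the hepatopancreas libraries (r over 0.95 and a highest level over 20 CPM), and these summed to between 12.2 and 9138 CPM in high-growth and to at most 64.6 CPM in low-growth hepatopancreas. In the mantle the sums lay closer, with a median of 69.1 CPM (up to 344) in high growth and of 56.1 CPM (up to 140) in low growth, and 3 of the 14 loci tested there rose. A candidate explanation is RNA of ovary tissue, which in abalone lies against the digestive gland, in the sampled piece: across these loci the Spearman rho between their mean level in high-growth hepatopancreas and each high-growth mantle library had a median of 0.691 (0.342 to 0.823), against 0.361 in low-growth mantle (0.0987 to 0.518). The ratios between these loci thus went with this explanation, while their sums in the mantle give it little support. These loci were chosen by their levels in the hepatopancreas libraries, so their sums there are no support for it. A difference in sex or maturity could give the same ratios in both tissues, so the rho does not tell these explanations apart. As the source of most other rises in the hepatopancreas it is argued against, since the 39 other loci that rose had a median r of 0.0236 with the vitellogenin-type loci within high growth. That lay above the median of −0.206 over all tested loci, and 7 of the 39 had an r over 0.7, so it stays open for some of them. A difference in sex or maturity between the groups, which the labels do not give, stays open, as untested.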
